A study of Homo sapiens with 90 samples.

How the data were processed

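RNA-seq libraries from 90 cultures of KOLF2.2J and lines edited from it, an established human induced pluripotent stem cell line, were taken from a public deposit. Per the labels' protocols, total RNA was taken on day 6 of differentiation and libraries were made with a kit that removes ribosomal RNA, and per the labels the lines for 6 factors were grown as primitive syncytium and those for ISL1 as extraembryonic mesenchyme. The series description counts more samples and assigns the factors to the culture schemes otherwise; the label of each sample was followed. Per the submitters' processing notes STAR, Salmon and featureCounts were used with the build GRCh38, with no version, order or annotation release given.

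The deposited count table holds whole-number counts of reads per Ensembl gene with no normalization, and a second deposited table holds counts of reads left out of it as unmapped, multimapping, without a feature or ambiguous. The deposited estimated counts per gene and per transcript, of the kind Salmon writes, are not whole numbers and carry no normalization. The deposited TPM values, scaled for transcript length, have the same total in each library. Whether counting used strand is not stated. Deposited tables that only round these estimates, and the TPM per transcript, were not used, and 0 sample columns were left over. Of 38592 gene identifiers, 38568 matched a symbol and 34390 a position in GENCODE v29, an annotation on GRCh38 that need not be the submitters' own; positions, exons and transcripts are from it, and the edited intervals from the labels.

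Gene counts per library totalled 14835233 to 26997080 for EPAS1, 20338199 to 29538633 for FOSB, 15833301 to 27412857 for GCM1, 19504485 to 30288621 for GRHL1, 17205399 to 22906243 for ISL1, 19844669 to 27229459 for POU2F3 and 18577800 to 25575258 for PPARG. Reads without a feature were 18.7% to 43.0% and mitochondrial genes 1.36% to 7.69% of counts. The GCM1 and PPARG libraries formed one numbered series, the GRHL1, POU2F3 and FOSB libraries another, and the EPAS1 and ISL1 libraries their own, so an effect of a library series cannot be separated from the experiment between these sets.

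Counts were fitted with edgeR 4.0.16 under R 4.3.3, once for each of 4 sets of libraries: GRHL1, POU2F3 and FOSB with a pooled wild type of 1 library named for each gene, EPAS1 at both oxygen levels, GCM1 with PPARG, and ISL1. Genes were kept by filterByExpr on the group, with the 7 targeted genes always kept, libraries were scaled by TMM, and a quasi-likelihood negative binomial model with robust shrinkage (glmQLFit on a trended dispersion) had group as its only term. Adjusted p-values are Benjamini-Hochberg over the genes tested with a threshold of 0.05, and standard errors are the fold change divided by the square root of F. A mutant comparison is the mean of the 3 strategies minus wild type; the strategies were compared with each other in a test with 2 degrees of freedom; interactions are differences between such contrasts. In all, 21 comparisons were tested. CPM printed for genes are on the TMM scale.

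Gene lists, 24 in number with 462 genes, were written from general knowledge: syncytiotrophoblast hormones and fusion, cytotrophoblast and trophoblast core, extravillous trophoblast, amnion-like, mesenchymal, pluripotency, hypoxia response, lipid handling and PPAR targets, epithelial junctions and GRHL targets, AP-1 and immediate early, cell cycle, tuft cell, cardiac and second heart field, endothelial, neural and neural crest, endoderm, p53 targets, integrated stress response, mitochondrially encoded, replication-dependent histones, imprinted and targeted transcription factors, with haematopoietic and primitive streak lists that never had 5 tested members and gave no test. LRMP, MT-RNR1 and MT-RNR2 had no match. Each list was tested in 13 comparisons with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison; of 286 tests 122 passed, and 7 of these with an estimated correlation: mesenchymal for FOSB, tuft cell for POU2F3, endothelial for GCM1, lipid handling for PPARG, and lipid handling, endothelial and cardiac for GCM1 against PPARG. Genes were named by rule: the targeted gene, up to 10 that rose and up to 10 that fell most among those past the threshold whose libraries do not overlap between the sides with a mean log2 CPM of at least 1, up to 4 members of each list with the smallest adjusted p, and for strategies the 5 with the smallest adjusted p, leaving out clone-style names and genes of the sex chromosomes that mark sex. The text prints a part of the genes so named, and several whose call ended when a single library was left out were not printed. The tests, lists, naming rule and most alternatives were chosen before the data were examined.

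The fit was tested on simulated counts with known changes. At planted changes of 1.5, 2, 4 and 8-fold it recovered 68%, 92%, 100% and 100% of genes for GRHL1, 36%, 74%, 98% and 100% for EPAS1 at 3% oxygen, 62%, 96%, 100% and 100% for GCM1 and 12%, 62%, 90% and 98% for ISL1, with 9 false calls among 20585 unchanged genes for GRHL1 and 5 among 19516 for ISL1. Between the libraries of a group, 90 pairs were compared by a chi-square statistic of their counts and 0 were identical. EPAS1 lines carry the same names at both oxygen levels, which pairs them by design; after removing group means the correlation of a line with itself ran from −0.24 to 0.61 and was the highest for 6 of 9 lines. Wild-type numbers were not taken as pairs: the own number was best for 2 of 3 across oxygen and 1 of 3 across the GCM1 and PPARG experiments.

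The alternatives to these choices were DESeq2 1.42.0 as the model, its size factors, no filter on low counts, estimated counts, the 12 libraries of a comparison alone, the lines of the other 2 genes together with wild type as control, the line or number as a block, TPM for the targeted genes, an estimated correlation for the lists, and leaving out each library. For comparisons across genes the samples were also regrouped into as many as 100 other splits. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest. Counts of paralogs with near-identical sequence, among them the CGB, PSG, CSH, LGALS and MT1 genes and the histones, and of overlapping or antisense genes are uncertain, since reads may have been divided between copies.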

Results

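RNA was sequenced from 90 cultures of KOLF2.2J, a human induced pluripotent stem cell line, and of lines made from it in which the gene of 1 of 7 transcription factors was edited. All were collected on day 6 of differentiation. Lines for GRHL1, POU2F3, FOSB, EPAS1, GCM1 and PPARG were labelled as grown into primitive syncytium, a culture model of the first multinucleated layer of the human placenta. Those for ISL1 were grown into extraembryonic mesenchyme, the supporting tissue beneath that layer. Every gene was disrupted in 3 ways: deletion of most or all of the coding sequence (KO), deletion of a critical exon (CE) and insertion of a stop codon (PTC). The 90 samples form 30 groups of 3. GRHL1, POU2F3 and FOSB had 1 wild-type culture each by library name (replicates 1, 2 and 3 in that order), pooled here as 3 shared ones, and GCM1, PPARG and ISL1 each had their own 3. The EPAS1 lines and their wild type were grown at both 20% and 3% oxygen.

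Total gene counts per library ran from 14835233 to 30288621, with a highest total of 26997080 in the EPAS1 and 22906243 in the ISL1 experiment. Each comparison set the 9 lines of a gene (n = 9, each editing strategy weighted equally) against wild type (n = 3) unless stated. Values after a log2 fold change are standard errors, and values after CPM, counts scaled to a common library total, are SDs. Adjusted p-values come from edgeR's quasi-likelihood F test for genes and from camera for lists. The 3 replicates of an edited group carry different line names, and those of wild type are described as biological replicates without further detail. The p-values measure spread between such cultures. A property of the edited clones unrelated to the deleted gene cannot be separated from the loss of that gene.

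The targeted genes come first, since their levels check the labels. GRHL1 (ENSG00000134317, GRCh38 chromosome 2, 9951693 to 10002277), a factor of epithelial barriers, averaged 366 ± 30.8 CPM in wild type. It fell to 12.3% of that in KO, 35.2% in CE and 27.8% in PTC lines (adjusted p = 2.5e-11, 5.1e-07 and 2.1e-08). POU2F3 (ENSG00000137709, chromosome 11, 120236640 to 120319944), known for specifying tuft cells, was at 31 ± 3.77 CPM in wild type. It fell to 2.41% in KO and 31.8% in CE lines (adjusted p = 9e-09 and 0.0016), while its 50.6% in PTC lines did not pass (adjusted p = 0.15). EPAS1 (ENSG00000116016, chromosome 2, 46293667 to 46386703) encodes the oxygen-regulated subunit HIF-2α. At 20% oxygen it fell from 1420 ± 603 CPM to 5.83%, 23.6% and 29.5% in KO, CE and PTC lines (adjusted p = 3.4e-07, 0.006 and 0.024). At 3% oxygen it fell from 935 ± 144 CPM to 6.39%, 22.7% and 31.6% (adjusted p = 1.5e-07, 5e-05 and 0.00056). FOSB (ENSG00000125740, chromosome 19, 45467995 to 45475179), an AP-1 subunit, fell from 268 ± 38.4 CPM to 13% in KO lines (adjusted p = 6.7e-05). Its levels in CE (67.3%) and PTC lines (151%) did not pass (adjusted p = 0.34 and 0.53). In the deposited transcript estimates FOSB-203 was at 102 ± 15.8 CPM in CE lines, 31.2 ± 1.22 in KO lines and 0 in wild type. The KO deletion takes all 1014 coding bases of FOSB-201, so the estimate for FOSB-203 alone does not show a shortened coding transcript. FOSB-201 was at 21.3 ± 11.1 in CE lines and 185 ± 14.6 in wild type. The CE deletion takes 321 of the 1014 coding bases of FOSB-201, a multiple of 3, so the reading frame may be kept. Protein was not measured, so a shortened FOSB in the CE lines remains possible.

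For GCM1 and PPARG the whole-gene count did not track the edit. GCM1 (ENSG00000137270, chromosome 6, 53126964 to 53148829), which drives trophoblast fusion, was at 437 ± 70 CPM in wild type. It rose to 147% and 189% in KO and CE lines and fell to 47% in PTC lines (adjusted p = 0.0013, 3.9e-06 and 5.1e-07). PPARG (ENSG00000132170, chromosome 3, 12287368 to 12434356), a nuclear receptor for lipids, was at 54.7 ± 3.64 CPM. It rose to 237% and 145% in KO and CE lines (adjusted p = 1.8e-09 and 0.00012), with 110% in PTC lines (adjusted p = 0.27), although in TPM, a measure that corrects for transcript length, the CE lines were at 97.3%. ISL1 (ENSG00000016082, chromosome 5, 51383391 to 51394738), a factor of heart and limb progenitors, was at 46.1 ± 2.89 CPM and fell to 41.5%, 39.1% and 32.5% (adjusted p = 0.032, 0.02 and 0.0092). The KO deletions left 908 of 2765 exonic bases in the GCM1 transcript, 682 of 1870 in PPARG and 1554 of 2459 in ISL1. Counts from outside the deleted part check nothing, and no annotated transcript of GRHL1, GCM1, PPARG or ISL1 lies wholly inside its KO deletion. For GCM1 the labels of the edited lines therefore went unchecked. For PPARG the transcript PPARG-214, which ends inside the KO deletion, was at 0 CPM in KO lines, 5.39 ± 0.45 in CE, 5.32 ± 1.08 in PTC lines and 5.9 ± 0.65 in wild type. The coding transcript PPARG-207 was at 0, 0.03 ± 0.06 and 0.19 ± 0.09 CPM in KO, CE and PTC lines and 5.26 ± 1.68 in wild type. Other coding transcripts, which also reach beyond the KO deletion, went otherwise. PPARG-202 was at 4.06 ± 0.67, 0.45 ± 0.43 and 0.92 ± 0.38 CPM in those lines and 6.63 ± 0.72 in wild type. PPARG-201 was at 11.84 ± 5.77, 0.37 ± 0.08 and 0.28 ± 0.25 CPM, and 0.95 ± 0.86 in wild type. Transcripts that do lie inside a deletion, 3 for EPAS1 and 1 each for FOSB and POU2F3, had 0 CPM in KO lines. Their wild-type means reached only 12 for EPAS1, 0.36 for FOSB and 1.81 for POU2F3.

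**Figure D1:**
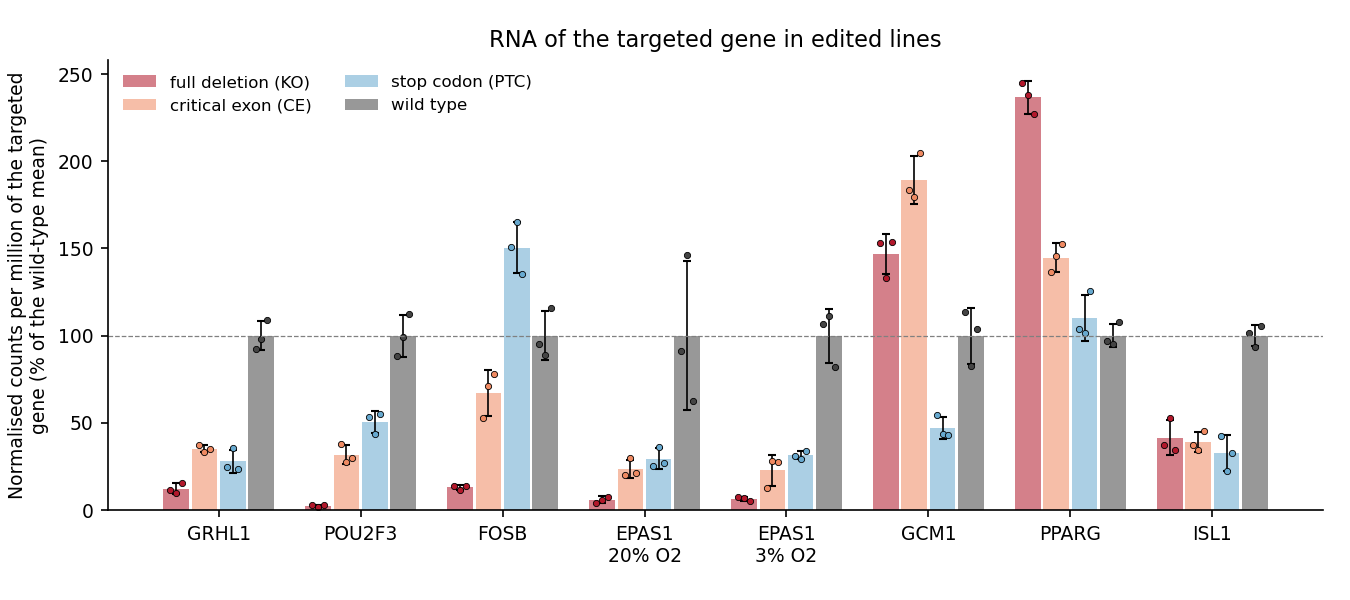
Level of each targeted gene in its KO, CE and PTC lines as a percent of the wild-type mean of normalised CPM, where bars are means of 3 libraries, error bars SD, points single libraries and the dashed line 100%. GRHL1, POU2F3, EPAS1 and ISL1 lie below wild type in every strategy, whereas GCM1 and PPARG lie above it in KO and CE lines.

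Loss of GRHL1 lowered the hormone and fusion genes of the syncytiotrophoblast and raised mesenchymal and proliferative ones. None of these lists passed with an estimated correlation (adjusted p = 0.29 for each). PAEP, which encodes the secreted protein glycodelin, fell from 11.4 ± 2.33 to 0.26 ± 0.11 CPM (−5.44 ± 0.21, adjusted p = 7.7e-17). SBSN, a gene of stratified epithelium (−6.27 ± 0.31, adjusted p = 4.2e-13), and CLIC3, a chloride channel gene abundant in placenta (−4.63 ± 0.29, adjusted p = 1.6e-10), fell as well. CYP19A1, the aromatase that makes placental oestrogen, fell from 1070 ± 157 to 275 ± 88.1 CPM (adjusted p = 2.4e-09). HOPX, a cofactor of differentiation, fell from 487 ± 109 to 73.8 ± 25.7 CPM (adjusted p = 5.1e-10), and the leptin gene LEP by −4.5 ± 0.61 (adjusted p = 5.8e-06). The growth factor receptor gene KDR rose (3.84 ± 0.43, adjusted p = 6.1e-08), as did the matrix gene THBS1 (3.14 ± 0.65, adjusted p = 0.00054). The collagen gene COL5A1 rose by 1.13 ± 0.12 (adjusted p = 3.9e-08). Junction genes went both ways. The claudin gene CLDN4 and the splicing regulator gene ESRP2 fell (−0.78 ± 0.08 and −0.68 ± 0.07), while the cadherin gene CDH3 rose (1.7 ± 0.16, adjusted p = 2.3e-08).

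Of 20885 genes tested for GRHL1, 4911 rose and 4878 fell. Of those that changed more than 2-fold, 901 rose and 2040 fell. In the list of syncytiotrophoblast hormones and fusion 0 of 31 genes rose and 27 fell, also when adjusted over the list alone (median −1.40, adjusted p = 3.1e-17, adjusted p = 0.29 with an estimated correlation). Among histones 14 of 15 rose and 0 fell, among cell-cycle genes 18 of 23 rose and 1 fell, and among mesenchymal genes 19 of 30 rose and 2 fell, each also when adjusted over the list alone. Those lists were higher (adjusted p = 5.9e-07, 1.1e-06 and 9.3e-06), each at adjusted p = 0.29 with an estimated correlation. The hypoxia response was lower (median −0.54, adjusted p = 0.00067, adjusted p = 0.65 with an estimated correlation). In it 1 of 34 genes rose and 18 fell (1 and 19 adjusted over the list alone). The p53 list did not pass (adjusted p = 0.055, adjusted p = 0.64 with an estimated correlation), with 11 of 20 genes higher and 2 lower (11 and 3 adjusted over the list alone). Against the lines of the other 2 genes plus wild type the hypoxia list no longer passed (adjusted p = 0.083). CDH2, the N-cadherin gene, rose against wild type (3.18 ± 1.11, adjusted p = 0.024), was at −0.22 against that control, and lost its call without wild-type replicate 1, 2 or 3 (adjusted p = 0.068, 0.074 and 0.081).

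Loss of POU2F3 went with fewer hormone, hypoxia and stress-response transcripts and more histone and cell-cycle transcripts than in the pooled wild type. None of these 5 lists passed with an estimated correlation (adjusted p = 0.25, 0.25, 0.25, 0.089 and 0.25). Against the lines of the other 2 genes plus wild type the hormone list turned to higher and the histone and cell-cycle calls ended (adjusted p = 0.53, 0.13 and 0.57). FLT1, the receptor gene whose soluble product is released by placenta, fell from 51 ± 19.4 to 8.75 ± 7.05 CPM (−2.61 ± 0.66, adjusted p = 0.013). LEP fell from 13.2 ± 2.72 to 3.86 ± 2.18 CPM (−1.81 ± 0.54, adjusted p = 0.026). DCLK1, a kinase gene used as a tuft-cell marker, fell (−1.53 ± 0.22, adjusted p = 0.0011). TRPM5, the taste-signalling channel gene of tuft cells, was at −1.05 and passed only with estimated counts (adjusted p = 0.083 and 0.022). The immediate early gene KLF4 (−1.11 ± 0.23, adjusted p = 0.0059), the serine synthesis gene PSAT1 (−0.95 ± 0.23, adjusted p = 0.011) and the glycolytic gene ALDOC (−1.15 ± 0.26, adjusted p = 0.0063) fell. KDR (2.88 ± 0.45, adjusted p = 0.0011), the collagen gene COL3A1 (1.21 ± 0.28, adjusted p = 0.0085) and the adhesion gene CDH11 (1.63 ± 0.32, adjusted p = 0.004) rose. So did the histone gene H2AC11 (0.65 ± 0.1, adjusted p = 0.0011). Without wild-type replicate 3 the calls of FLT1, LEP, COL3A1, ALDOC, KLF4 and PSAT1 ended (adjusted p = 0.098, 0.14, 0.073, 0.062, 0.074 and 0.14). Without wild-type replicate 1 those of LEP and COL3A1 ended (adjusted p = 0.068 and 0.061).

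In the POU2F3 lines 2175 genes rose and 1782 fell, a share of 55% higher that became 44.8% with DESeq2's size factors, so no balance between directions can be read. Of 31 syncytiotrophoblast hormone and fusion genes 0 rose and 15 fell (0 and 23 adjusted over the list alone). Of 34 hypoxia genes 1 rose and 16 fell (1 and 24 adjusted over the list alone), and of 16 stress-response genes 0 rose and 9 fell (0 and 11 adjusted over the list alone). The 3 lists were lower (adjusted p = 3.8e-10, 4.2e-10 and 1.3e-06), each at adjusted p = 0.25 with an estimated correlation. The tuft cell list was lower too (1 and 2 of 8, and 1 and 3 adjusted over the list alone), at adjusted p = 0.0019 and at adjusted p = 0.049 with an estimated correlation. Its mean log2(CPM + 0.5) was 0.19 in KO, 0.33 in CE and 0.47 in PTC lines, and 0.47 to 0.56 in the wild-type libraries. Any part that the fall of POU2F3 itself has in this call and in the order of these means was not tested. Histones were higher, with 11 of 15 that rose and 0 that fell (12 and 0 adjusted over the list alone, adjusted p = 3.8e-10, adjusted p = 0.089 with an estimated correlation). So was the cell-cycle list, with 14 of 23 that rose and 0 that fell, also when adjusted over the list alone (adjusted p = 2e-06, adjusted p = 0.25 with an estimated correlation). Mesenchymal genes were higher too, with 10 of 30 that rose and 3 that fell (13 and 3 adjusted over the list alone, adjusted p = 0.0028, adjusted p = 0.42 with an estimated correlation). Against the lines of the other 2 genes plus wild type the mesenchymal list was lower (adjusted p = 1.3e-10), the syncytiotrophoblast list turned to higher (adjusted p = 0.53) and the histone and cell-cycle calls ended (adjusted p = 0.13 and 0.57). In mean log2(CPM + 0.5) of the mesenchymal list the GRHL1 lines ran from 3.5 to 4.2 and the FOSB lines from 3.36 to 4.48. The POU2F3 lines ran from 3.0 to 3.71 and wild type from 2.69 to 3.03. The turn of that list is thus relative to other edited lines and not to wild type alone. That control put DCLK1 at 0.21, KDR at −0.75, COL3A1 at −0.70 and CDH11 at −0.33, and ended the calls of FLT1 and LEP (adjusted p = 0.058 and 0.98). The count of called genes was 490 without wild-type replicate 3, 884 without wild-type replicate 1, 2397 without KO replicate 2 and 2542 without CE replicate 2. For CE replicates 1 and 2 the line in the library name is that of the other one's title, so which line each is remains unclear.

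Loss of FOSB went with more mesenchymal and cardiac transcripts in cultures labelled as trophoblast. As mean log2(CPM + 0.5), the mesenchymal list was at 4.07 in KO, 3.93 in CE and 3.42 in PTC lines. The cardiac list was at 1.47, 1.37 and 0.93. GRHL1 lines, set against the same wild type, ran from 3.5 to 4.2 in the mesenchymal list. With an estimated correlation the mesenchymal list passed and the cardiac one did not (adjusted p = 0.015 and 0.087). RELN, which encodes the guidance protein reelin, rose (7.05 ± 1.41, adjusted p = 0.0064). KDR rose from 0.2 ± 0.06 to 5.44 ± 2.59 CPM (4.63 ± 0.42, adjusted p = 2.2e-07). COL3A1 rose from 27.3 ± 9.69 to 161 ± 73.6 CPM (2.48 ± 0.3, adjusted p = 9.7e-05). The type I collagen gene COL1A1 (1.08 ± 0.18, adjusted p = 0.0011), the filament gene VIM (2.81 ± 0.58, adjusted p = 0.0079) and the cardiac myosin gene MYL4 (1.41 ± 0.31, adjusted p = 0.0087) rose too. The cytokine receptor genes IL7R (−1.69 ± 0.28, adjusted p = 0.0013) and IL31RA (−1.5 ± 0.23, adjusted p = 0.00051) fell. So did DCLK1 (−1.32 ± 0.22, adjusted p = 0.0011) and the AP-1 gene FOSL1 (−0.69 ± 0.15, adjusted p = 0.0066). Without wild-type replicate 1 the calls of RELN, VIM and MYL4 ended (adjusted p = 0.056, 0.075 and 0.063), and without wild-type replicate 3 those of MYL4 and FOSL1 (adjusted p = 0.053 and 0.068).

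For FOSB 595 genes rose and 553 fell. Of 30 mesenchymal genes 19 rose and 0 fell (24 and 0 adjusted over the list alone). The list was higher (median 1.03, adjusted p = 3.1e-23) and stayed so at adjusted p = 0.015 with an estimated correlation. Of 17 cardiac and second heart field genes 7 rose and 0 fell (13 and 0 adjusted over the list alone, median 1.33, adjusted p = 8.2e-08, adjusted p = 0.087 with an estimated correlation). The amnion-like list was higher, with 6 of 17 that rose and 0 that fell (8 and 1 adjusted over the list alone, adjusted p = 0.0091, adjusted p = 0.35 with an estimated correlation). The hypoxia list was lower with 1 of 34 that rose and 1 that fell, also when adjusted over the list alone (median −0.25, adjusted p = 0.0061, adjusted p = 0.68 with an estimated correlation), and not without wild-type replicate 3 (adjusted p = 0.33). Against the lines of the other 2 genes plus wild type both of these turned (adjusted p = 0.97 and 0.0027), DCLK1 was at 0.51 and 6436 genes were called, while the 12 libraries of FOSB and its wild type alone gave 745. The count was 208 without wild-type replicate 1, 530 without wild-type replicate 2, 731 without KO replicate 2, 713 without CE replicate 1, 755 without PTC replicate 3 and 1781 without PTC replicate 2.

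GRHL1, POU2F3 and FOSB shared their wild-type libraries, so an error in those 3 enters all 3 comparisons. Genes that rose with loss of GRHL1 and with loss of POU2F3 numbered 1976, and genes that fell in both 1484. No overlap expected from the shared controls alone was computed. Across the 20885 genes the fold changes correlated at r = 0.77 for GRHL1 and POU2F3, 0.65 for GRHL1 and FOSB and 0.67 for POU2F3 and FOSB. Simulated data with shared controls and no effects gave 0.76 for each pair. These correlations therefore neither show nor exclude a shared effect, and those with FOSB lie below that value. The covariance, which the shared controls alone held at 0.0581 or less in 20 simulations, was 0.256, 0.207 and 0.132. It lay above the simulations for each pair, which a shared effect or wild types that deviate as a whole may both give. By name each gene's experiment has 1 of these libraries, so its own control would have no spread between replicates, and differences between the 3 experiments enter the pooled control.

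At 20% oxygen the loss of EPAS1 changed few single genes, while the hypoxia list was higher (adjusted p = 0.45 with an estimated correlation). SERPINB9, which encodes a granzyme inhibitor, fell from 835 ± 283 to 413 ± 47.2 CPM (−1.02 ± 0.16, adjusted p = 0.0044). The leukotriene receptor gene CYSLTR2 (−1.28 ± 0.19, adjusted p = 0.0026) and the growth factor receptor gene PDGFRA (−1.44 ± 0.24, adjusted p = 0.0065) fell. So did the death ligand gene TNFSF10 (−3.46 ± 0.64, adjusted p = 0.014). ATP12A, a proton pump gene, rose (1.9 ± 0.26, adjusted p = 0.0014), as did P4HA2, a collagen hydroxylase gene that hypoxia induces (1.26 ± 0.22, adjusted p = 0.0077). Of 20967 genes 39 rose and 52 fell. The hypoxia list was higher, not lower (median 0.59, adjusted p = 2e-18, adjusted p = 0.45 with an estimated correlation), with 4 of 34 that rose and 0 that fell (16 and 0 adjusted over the list alone). Its mean log2(CPM + 0.5) was 4.93 to 5.92 in KO, 6.02 to 6.29 in CE and 5.55 to 5.99 in PTC lines. Wild type ran from 4.96 to 5.68, so the KO and PTC ranges overlap with it.

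The count at 20% oxygen was 282 with DESeq2 and 191 with the 12 libraries of that oxygen level alone. Without the expression filter TNFSF10 did not pass (adjusted p = 0.077). Without wild-type replicate 1 the calls of CYSLTR2, SERPINB9, TNFSF10 and P4HA2 ended (adjusted p = 0.076, 0.066, 0.094 and 0.11), and without wild-type replicate 2 those of SERPINB9, TNFSF10 and PDGFRA (adjusted p = 0.062, 0.14 and 0.1). The count of 91 was 225 and 53 without KO replicates 1 and 2, 40, 48 and 44 without CE replicates 1, 2 and 3, 60, 56 and 38 without PTC replicates 1, 2 and 3, and 7 and 43 without wild-type replicates 1 and 2.

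At 3% oxygen the loss of EPAS1 gave more hormone transcripts and fewer of the receptor genes FLT1 and PDGFRA. The hormone list did not pass with an estimated correlation (adjusted p = 0.34). LGALS13, the placental galectin 13 gene (2.52 ± 0.24, adjusted p = 1.8e-07), and CGB3, a chorionic gonadotropin gene (2.12 ± 0.24, adjusted p = 1.6e-06), rose. So did the relaxin-family hormone gene INSL4 (1.9 ± 0.22, adjusted p = 1.7e-06) and the protease inhibitor gene SERPINB2 (3.39 ± 0.22, adjusted p = 4.7e-09). FLT1 fell from 355 ± 141 to 11.1 ± 10.4 CPM (−5.19 ± 0.51, adjusted p = 2.6e-07). TNFSF10 fell from 85.4 ± 15 to 1.93 ± 3.1 CPM (−5.79 ± 0.59, adjusted p = 4e-07), and PDGFRA fell as well (−2.74 ± 0.21, adjusted p = 2.1e-08). The glycolytic genes PGK1 (1.15 ± 0.19, adjusted p = 0.0001) and ENO2 (2.9 ± 0.54, adjusted p = 0.00035) rose. The acyl-CoA synthetase gene ACSL1 (1.53 ± 0.14, adjusted p = 1.3e-07) and the cystine transporter gene SLC7A11 (1.63 ± 0.19, adjusted p = 1.8e-06) rose too.

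In total 3593 genes rose and 2753 fell with the loss of EPAS1 at 3% oxygen. Of 31 syncytiotrophoblast hormone and fusion genes 23 rose and 1 fell, also when adjusted over the list alone (median 0.97, adjusted p = 1.3e-13, adjusted p = 0.34 with an estimated correlation). Of 16 stress-response genes 12 rose and 0 fell (16 and 0 adjusted over the list alone, median 1.23, adjusted p = 3.8e-07, adjusted p = 0.37 with an estimated correlation). Of 26 genes of lipid handling 11 rose and 0 fell, also when adjusted over the list alone (adjusted p = 3.2e-05, adjusted p = 0.37 with an estimated correlation). The hypoxia list was again higher, with 16 of 34 that rose and 1 that fell (17 and 1 adjusted over the list alone, adjusted p = 0.00061, adjusted p = 0.65 with an estimated correlation). The amnion-like list was lower, with 1 of 17 that rose and 9 that fell (2 and 9 adjusted over the list alone, adjusted p = 0.00037, adjusted p = 0.37 with an estimated correlation). Without wild-type replicate 2 at 3% oxygen 3771 genes were called.

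Lower oxygen went with fewer hormone transcripts in wild-type cultures, though that list did not pass with an estimated correlation (adjusted p = 0.13). In wild type the chorionic gonadotropin gene CGB5 fell from 231 ± 133 to 8.85 ± 1.74 CPM (−4.71 ± 0.34, adjusted p = 1.9e-09). INSL4 fell from 80.8 ± 5.79 to 4.43 ± 1.55 CPM (−4.19 ± 0.26, adjusted p = 2.3e-10). The mitochondrial respiratory gene MT-CO2 fell from 5380 ± 269 to 1050 ± 451 CPM (adjusted p = 1.1e-07). TP63 and YAP1, factors of the proliferating trophoblast, rose (2.2 ± 0.27 and 1.3 ± 0.12, adjusted p = 1.6e-06 and 5.8e-08). The carbonic anhydrase gene CA3 (4.36 ± 0.55, adjusted p = 2.3e-06) and the oxygen sensor gene EGLN3 (1.67 ± 0.37, adjusted p = 0.0011) rose. In the EPAS1 lines CGB5 (−2.97 ± 0.18, adjusted p = 8.9e-11) and INSL4 (−2.67 ± 0.14, adjusted p = 9.1e-12) fell too. CYP1A1, a target of the aryl hydrocarbon receptor, rose in them (2.75 ± 0.19, adjusted p = 6.4e-10). FLT1 rose in wild type (2.41 ± 0.69, adjusted p = 0.0075) and fell in the EPAS1 lines (−2.01 ± 0.41, adjusted p = 0.00037).

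Wild type at 3% oxygen (n = 3) against 20% (n = 3) had 4481 genes higher and 4651 lower, and the EPAS1 lines (n = 9 at each level) 5350 and 4525. All 13 mitochondrially encoded genes tested fell in both, also when adjusted over the list alone. The list test gave adjusted p = 1.4e-13 in wild type and 6.9e-24 in the mutants, and adjusted p = 0.25 and 0.084 with an estimated correlation. The mitochondrial share of counts in wild type was 2.2% ± 0.86 at 3% and 5.39% ± 0.29 at 20% oxygen. Of 31 syncytiotrophoblast genes 0 rose and 26 fell in wild type (1 and 27 adjusted over the list alone, median −1.72, adjusted p = 5.6e-19, adjusted p = 0.13 with an estimated correlation). In the mutants 0 rose and 26 fell (1 and 26 adjusted over the list alone, median −0.89, adjusted p = 3.6e-18, adjusted p = 0.084 with an estimated correlation). Other lists were higher at 3% oxygen. In wild type 12 of 17 amnion-like genes rose and 1 fell, also when adjusted over the list alone, and 17 of 29 mesenchymal genes rose and 4 fell (18 and 4 adjusted over the list alone). These 2 lists gave adjusted p = 0.0032 and 0.0078, and adjusted p = 0.47 and 0.52 with an estimated correlation. The endothelial list in the mutants had 0 of 9 that rose and 4 that fell, also when adjusted over the list alone. Its median was above 0 (0.05) while its mean (−0.52) and its test were below (adjusted p = 0.02, adjusted p = 0.38 with an estimated correlation). The share of reads assigned to no feature was 41.5% ± 1.86 at 3% and 32.7% ± 0.6 at 20% oxygen in wild type. Oxygen level and the day or incubator of culture cannot be told apart from the labels.

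Whether the effect of losing EPAS1 depends on oxygen was tested as an interaction. Several hormone genes that low oxygen reduced were reduced less without EPAS1. In the syncytiotrophoblast list 9 of 31 genes were positive and 1 negative, and the list did not pass with an estimated correlation (adjusted p = 0.48). The difference in log2 fold change between 3% and 20% oxygen was 1.53 ± 0.27 for INSL4 (adjusted p = 0.0022), 1.8 ± 0.29 for LGALS13 (adjusted p = 0.0011) and 1.99 ± 0.33 for the gonadotropin gene CGB8 (adjusted p = 0.0014). It was 2.69 ± 0.26 for the serpin gene SERPINB7 (adjusted p = 5e-06) and 2.54 ± 0.25 for SERPINB2 (adjusted p = 7.2e-06). The membrane protease gene TMPRSS2 (2.02 ± 0.21, adjusted p = 8.6e-06) and the apolipoprotein gene APOB (2.57 ± 0.37, adjusted p = 0.00046) followed. FLT1 went the opposite way (−4.42 ± 0.82, adjusted p = 0.0033). EPAS1 itself gave a difference of 0.06 ± 0.35 that did not pass (adjusted p = 0.95).

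A positive difference was called for 726 genes and a negative one for 205. The counts of the syncytiotrophoblast list were 19 and 1 adjusted over the list alone (median 0.84, adjusted p = 4.4e-12). Of 16 stress-response genes 3 were positive and 0 negative (4 and 0 adjusted over the list alone, adjusted p = 0.00035, adjusted p = 0.83 with an estimated correlation). Of 26 genes of lipid handling 5 were positive and 0 negative (6 and 0 adjusted over the list alone, adjusted p = 0.00046, adjusted p = 0.61 with an estimated correlation). Of 8 endoderm genes 2 were positive and 0 negative, also when adjusted over the list alone (adjusted p = 0.017, adjusted p = 0.61 with an estimated correlation). The endoderm call ended with estimated counts (adjusted p = 0.056) and without wild-type replicate 2 at 20% oxygen (adjusted p = 0.081). The count of 931 was 608 without the expression filter, 1485 with DESeq2 and 2292 without CE replicate 1 at 3% oxygen. At 3% it was lower without PTC replicate 1 (538) or 3 (614) or wild-type replicate 1 (319) or 2 (266). At 20% it was lower without CE replicate 3 (567), PTC replicate 2 (570) or 3 (600) or wild-type replicate 1 (341) or 2 (586).

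**Figure D2:**
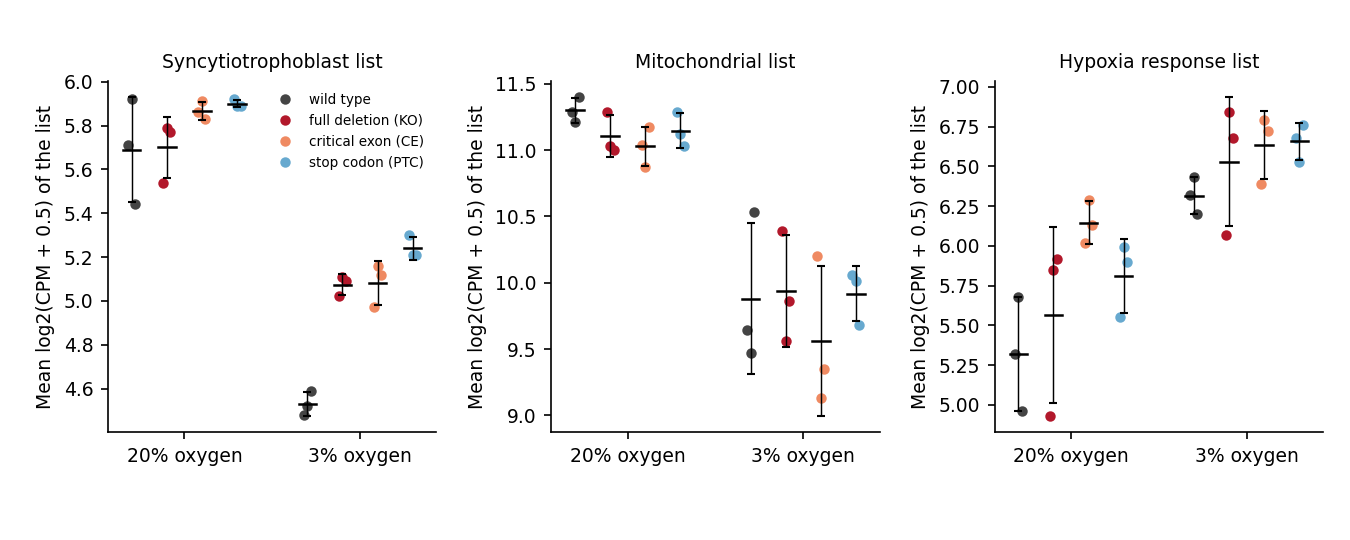
Mean log2(CPM + 0.5) over 3 gene lists in wild-type and EPAS1 KO, CE and PTC cultures at 20% and 3% oxygen, where points are libraries, bars the mean of 3 and error bars SD. The syncytiotrophoblast list is lower at 3% oxygen in every genotype, with a median change of −1.72 in wild type and −0.89 in the mutants.

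The 3 editing strategies were compared within each gene to ask whether the kind of edit matters beyond loss of the gene. Few genes differed, and most of those in the EPAS1 lines lay next to EPAS1. At 20% oxygen the membrane protein gene TMEM247 was at 10.1 CPM in KO lines against 0.07 and 0.05 in CE and PTC lines (adjusted p = 6.4e-10). The proton pump gene ATP6V1E2 was at 29.9 against 1.44 and 1.37 CPM (adjusted p = 4.8e-07), and the small GTPase gene RHOQ at 52.8 against 19.4 and 18.7 CPM (adjusted p = 0.0023). At 3% oxygen TMEM247 was at 9.15, 0.02 and 0.09 CPM (adjusted p = 9.7e-10) and RHOQ at 43, 9.06 and 13.9 CPM (adjusted p = 2.6e-05). In the GRHL1 lines KLF11, a repressor gene downstream of GRHL1, was at 35.8 CPM in KO lines against 9.7 and 10.4 (adjusted p = 2.7e-07). In the POU2F3 lines the upstream gene OAF was at 5.7 CPM in KO lines against 15.8 and 14.1 (adjusted p = 1.9e-05). Among FOSB lines SOCS3, a feedback inhibitor of cytokine signalling, differed away from the edit (adjusted p = 0.00082).

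Genes past the threshold between strategies numbered 7 for GRHL1, 2 for POU2F3, 26 for FOSB, 8 and 9 for EPAS1 at 20% and 3% oxygen, 2 for GCM1 and 1 for PPARG. Each of these counts includes the targeted gene, which the edits change directly, so the 1 for PPARG is PPARG itself. For POU2F3 and GCM1 the other gene lies within 300 kb of the target. For ISL1 edgeR called 0, with 211 genes at an unadjusted p under 0.05 and 2 called by DESeq2. Within 300 kb of the target, a region examined after these genes were seen, 7 of the 11 other tested genes differed for EPAS1 at 20% and again at 3% oxygen, all downstream, 3 of 9 for GRHL1 and 0 of 20 for FOSB. For POU2F3 it was 1 of 7, for GCM1 1 of 7 and for PPARG 0 of 6. ATP6V1E2 and RHOQ-AS1 lie on the strand opposite to EPAS1, and the labels do not say that counting used strand. In the deposited transcript estimates ATP6V1E2 was at 0.33 CPM in KO lines and 1.07 in CE lines and no longer differed (adjusted p = 0.76). With the 12 libraries at 20% oxygen alone RHOQ did not pass (adjusted p = 0.2). DESeq2 called 171 genes for GRHL1, 5 for POU2F3, 176 for FOSB, 32 for EPAS1 at 3% oxygen, 4 for GCM1 and 113 for PPARG, and estimated counts gave 4 for GRHL1 and 79 for FOSB. For PPARG 4 were called without the expression filter and 2 with its own 12 libraries. The GRHL1 count was 3383 without PTC replicate 2 and 4 without KO replicate 1, PTC replicate 1 or PTC replicate 3. The EPAS1 count was 3949 at 3% without CE replicate 1 and 14 at 20% without KO replicate 3. The FOSB count was 14 without KO replicate 1, 43 without KO replicate 3, 8 without CE replicate 1 or 2 and 16 without PTC replicate 1. The PPARG count was 467 without CE replicate 1, 3 without KO replicate 2 and 2 without KO replicate 3 or CE replicate 2 or 3.

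**Figure D3:**
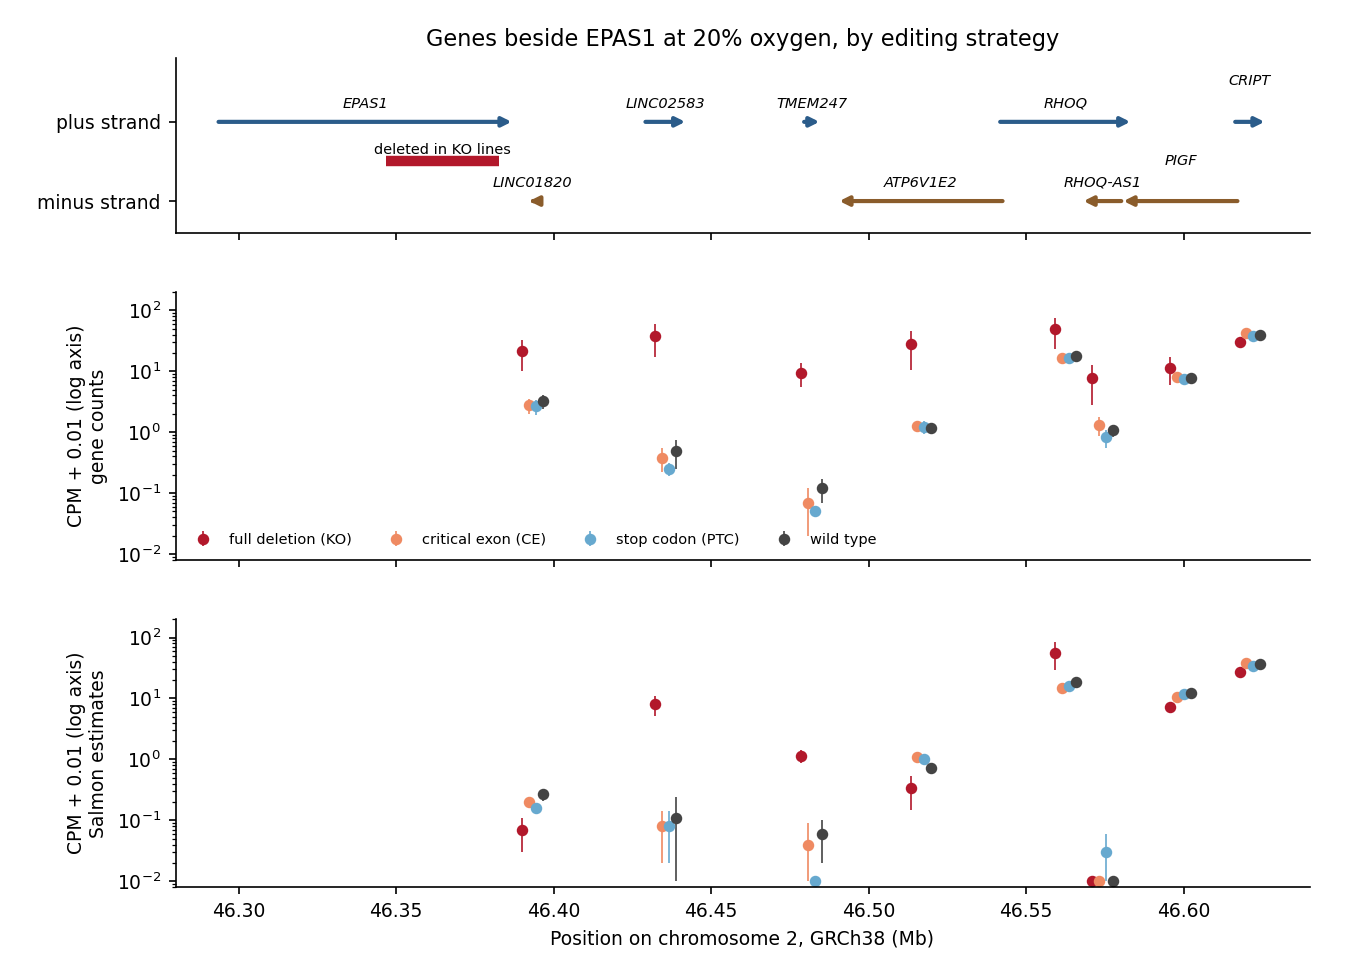
Genes around EPAS1 on chromosome 2 with their strand and the part deleted in KO lines (top), and CPM + 0.01 on a log axis of each gene at its midpoint from gene counts (middle) and from transcript estimates (bottom) at 20% oxygen, where points are means of 3 lines and bars SD. RHOQ is higher in KO lines in both, ATP6V1E2 in gene counts alone.

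Loss of GCM1 went with lower levels of most syncytiotrophoblast genes and higher levels of several genes of its progenitor. With an estimated correlation neither the syncytiotrophoblast list nor the cytotrophoblast list, in which 15 of 25 rose and 7 fell, passed (adjusted p = 0.065 and 0.32). LMO2, a transcriptional adaptor gene of blood and vessels, went from 40.6 ± 8.3 to 0.02 ± 0.04 CPM (−11.17 ± 0.33, adjusted p = 2.1e-15). BGN, a matrix proteoglycan gene, fell from 260 ± 89.1 to 0.41 ± 0.07 CPM (−9.29 ± 0.22, adjusted p = 3e-17). PLAC4, a placental transcript, fell from 376 ± 165 to 1.71 ± 0.38 CPM (adjusted p = 3.1e-17). The placental growth factor gene PGF (−4.18 ± 0.12, adjusted p = 3e-18), the syncytial surface gene SDC1 (−4.58 ± 0.16, adjusted p = 1.3e-15) and the vascular cadherin gene CDH5 (−5.86 ± 0.16, adjusted p = 5.8e-17) fell. Among the other targeted factors FOSB fell from 188 ± 59.8 to 8.83 ± 2.12 CPM (adjusted p = 4.4e-13). POU2F3 fell from 27.1 ± 8.9 to 1.36 ± 0.27 CPM (adjusted p = 3.6e-14). TP63, the marker of the proliferating progenitor (3.03 ± 0.25, adjusted p = 2.5e-09), and ELF5, a trophoblast stem cell factor gene (2.04 ± 0.14, adjusted p = 1.6e-11), rose. The chemokine gene CXCL12 (3.39 ± 0.24, adjusted p = 6.3e-11) and the imprinted gene PEG10 (1.81 ± 0.16, adjusted p = 2.1e-09) rose as well.

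For GCM1 5317 of 20216 genes rose and 5159 fell. Of those that changed more than 2-fold, 1051 rose and 2636 fell. Of 30 syncytiotrophoblast hormone and fusion genes 1 rose and 23 fell (2 and 25 adjusted over the list alone, median −2.18, adjusted p = 3.8e-28, adjusted p = 0.065 with an estimated correlation). Of 7 endothelial genes 0 rose and 5 fell, also when adjusted over the list alone (median −1.60). That list was lower at adjusted p = 2.4e-06, and at adjusted p = 0.018 with an estimated correlation. Of 18 extravillous trophoblast genes 2 rose and 10 fell, also when adjusted over the list alone (adjusted p = 0.0058, adjusted p = 0.3 with an estimated correlation). All 14 histone genes tested rose, also when adjusted over the list alone (median 1.17, adjusted p = 7.9e-09, adjusted p = 0.3 with an estimated correlation). Of 25 cytotrophoblast genes 15 rose and 7 fell, also when adjusted over the list alone (median 0.48, adjusted p = 0.0071, adjusted p = 0.32 with an estimated correlation).

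Loss of PPARG lowered lipid genes and part of the hormone set. The lipid list passed with an estimated correlation and the hormone list did not (adjusted p = 0.0052 and 0.4). AKR1B1, the aldose reductase gene, fell from 703 ± 90.8 to 51 ± 5.2 CPM (−3.79 ± 0.12, adjusted p = 2.1e-16). SLC27A2, a fatty acid transporter gene, fell from 299 ± 34.1 to 43.9 ± 6.79 CPM (−2.78 ± 0.1, adjusted p = 7.2e-16). TRHDE, a peptidase gene, fell from 37 ± 1.99 to 1.24 ± 0.58 CPM (−4.88 ± 0.19, adjusted p = 4.4e-14). PLIN4, which encodes a coat protein of lipid droplets (−2.41 ± 0.18, adjusted p = 1.4e-10), CGB5 (−3.42 ± 0.26, adjusted p = 1.2e-08) and LEP (−4.45 ± 0.44, adjusted p = 3e-07) fell. The secreted matrix genes FBLN2 (2.61 ± 0.2, adjusted p = 7.7e-10) and CCN4 (3.04 ± 0.25, adjusted p = 9.1e-10) rose. In all, 3792 genes rose and 4814 fell. Of 26 genes of lipid handling and PPAR targets 1 rose and 18 fell (1 and 19 adjusted over the list alone). That list was lower (median −0.96, adjusted p = 2.1e-10), also at adjusted p = 0.0052 with an estimated correlation. Of 30 syncytiotrophoblast genes 3 rose and 18 fell, also when adjusted over the list alone (median −0.73, adjusted p = 2.5e-06, adjusted p = 0.4 with an estimated correlation). Of 28 mesenchymal genes 17 rose and 5 fell (19 and 5 adjusted over the list alone, median 0.71, adjusted p = 0.0086, adjusted p = 0.35 with an estimated correlation). Of 22 AP-1 and immediate early genes 2 rose and 14 fell (3 and 15 adjusted over the list alone, adjusted p = 0.0023, adjusted p = 0.35 with an estimated correlation). Of 13 pluripotency genes 8 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.0023, adjusted p = 0.3 with an estimated correlation).

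The effects of losing GCM1 and PPARG were set against each other, each relative to its own wild type. Loss of GCM1 took more from PGF (difference in log2 fold change −3.86 ± 0.2, adjusted p = 5e-13). For SLC27A2, which fell with loss of PPARG and not with loss of GCM1, the difference was 3.43 ± 0.17 (adjusted p = 2.3e-13). ELF5 (3.48 ± 0.19, adjusted p = 2.5e-12) and PEG10 (3.61 ± 0.22, adjusted p = 8e-12) were raised by loss of GCM1 relative to loss of PPARG. Differences were positive for 4310 genes and negative for 3656. Of 30 syncytiotrophoblast genes 5 were positive and 21 negative, also when adjusted over the list alone (median −1.76, adjusted p = 2.1e-11, adjusted p = 0.15 with an estimated correlation). Of 7 endothelial genes 1 was positive and 5 negative, of 12 cardiac genes 0 and 6, and of 26 genes of lipid handling 17 and 2, each also when adjusted over the list alone. Those 3 lists passed (adjusted p = 3.4e-05, 0.00019 and 6.6e-08), and so at adjusted p = 0.0086, 0.0065 and 0.0065 with an estimated correlation. Of 28 genes of epithelial junctions 14 were positive and 5 negative, also when adjusted over the list alone (adjusted p = 0.0088, adjusted p = 0.44 with an estimated correlation). With estimated counts that call ended (adjusted p = 0.06).

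**Figure D4:**
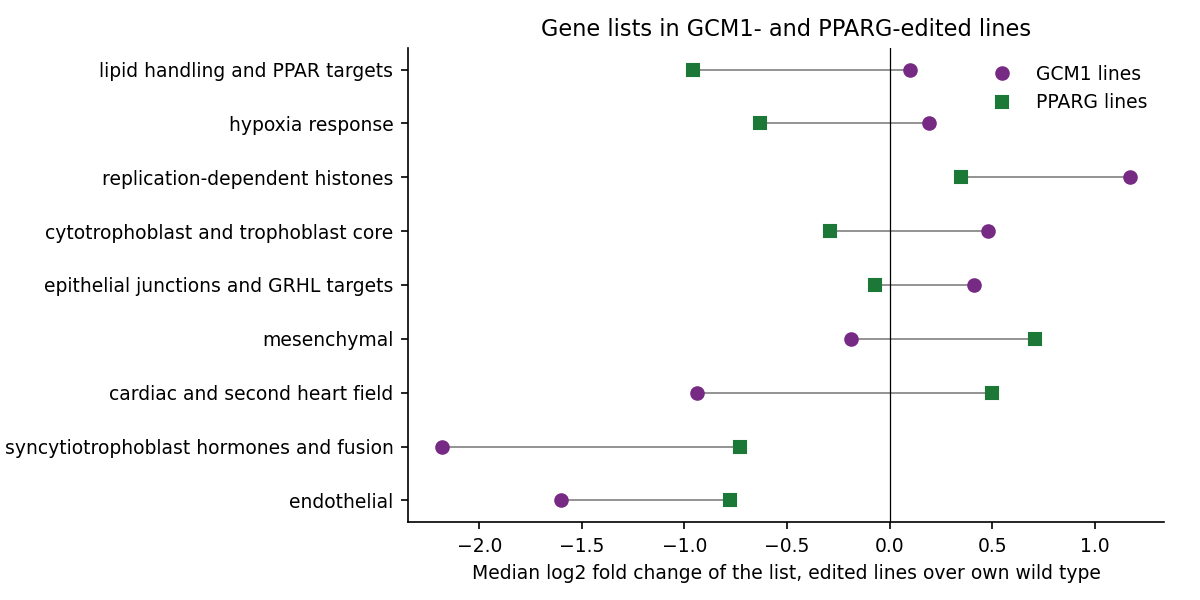
Median log2 fold change, mutant lines against their own wild type, of the 9 gene lists whose change differed between loss of GCM1 (circles) and loss of PPARG (squares), of which lipid handling, endothelial and cardiac also passed with an estimated correlation. The syncytiotrophoblast list lies at −2.18 for GCM1 and −0.73 for PPARG.

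The wild types of the GCM1 and PPARG experiments (n = 3 each), unedited cultures of one line, also differed from each other. The carbonic anhydrase gene CA3 (−3.02 ± 0.46, adjusted p = 0.0015), the glucose transporter gene SLC2A3 (−1.52 ± 0.32, adjusted p = 0.012) and the collagen gene COL5A2 (−0.90 ± 0.11, adjusted p = 0.00011) were lower in the GCM1 wild type. In total 76 genes were higher and 535 lower. The hypoxia list was lower, with 0 of 34 genes higher and 9 lower (0 and 24 adjusted over the list alone, median −0.67, adjusted p = 6e-17, adjusted p = 0.082 with an estimated correlation). In the imprinted list 0 of 17 were higher and 2 lower (0 and 3 adjusted over the list alone, adjusted p = 0.023, adjusted p = 0.082 with an estimated correlation). SLC2A3 lost its call without GCM1 wild-type replicate 2 or 3 (adjusted p = 0.082 and 0.084), and the imprinted list its call without replicate 2 (adjusted p = 0.068). The count was 990 with DESeq2, 1772, 182 and 151 without GCM1 wild-type replicates 1, 2 and 3, and 202 and 238 without PPARG wild-type replicates 1 and 3.

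In the mesenchyme cultures loss of ISL1 lowered single genes of the mesenchyme, among them LUM and COL3A1. SLITRK6, a neurite regulator gene, fell from 147 ± 8.4 to 6.7 ± 2.34 CPM (−4.47 ± 0.23, adjusted p = 8.2e-06). LUM, which encodes the proteoglycan lumican, fell from 219 ± 13 to 24.3 ± 6.95 CPM (−3.17 ± 0.23, adjusted p = 6.1e-05). COL3A1 fell from 514 ± 37.9 to 97.9 ± 13.2 CPM (−2.39 ± 0.11, adjusted p = 3.3e-06). The peptidase gene NAALAD2 (−3.33 ± 0.13, adjusted p = 2.6e-06) and the growth factor carrier gene IGFBP3 (−1.43 ± 0.07, adjusted p = 5e-06) fell too. The hemidesmosome collagen gene COL17A1 (1.68 ± 0.18, adjusted p = 0.00063) and the trophoblast surface gene TACSTD2 (1.15 ± 0.15, adjusted p = 0.0021) rose. Lines differed widely in trophoblast transcripts. GCM1 averaged 58 ± 71.2 CPM in mutants (6.55 ± 2.74, adjusted p = 0.23) and SDC1 437 ± 464 CPM (3.11 ± 1.22, adjusted p = 0.21), and neither passed, though DESeq2 called both (adjusted p = 0.019 and 0.023).

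For ISL1 193 of 19816 genes rose and 442 fell. Of 29 mesenchymal genes 0 rose and 5 fell (0 and 10 adjusted over the list alone, median −0.45, adjusted p = 1.7e-08, adjusted p = 0.44 with an estimated correlation). Of 23 cell-cycle genes 0 rose and 5 fell (0 and 9 adjusted over the list alone, adjusted p = 0.0025, adjusted p = 0.51 with an estimated correlation). Of 8 neural and neural crest genes 0 rose and 1 fell (0 and 3 adjusted over the list alone, adjusted p = 0.022, adjusted p = 0.46 with an estimated correlation). The syncytiotrophoblast list was higher with 1 of 31 that rose and 0 that fell (2 and 0 adjusted over the list alone, median 5.28, adjusted p = 1.2e-05, adjusted p = 0.46 with an estimated correlation). With the mean of that list as a covariate the neural call ended (adjusted p = 0.11), and so did that of the list itself (adjusted p = 0.43), which this covariate brings about by construction. The mitochondrially encoded list was higher, with 1 of 13 that rose and 0 that fell (4 and 0 adjusted over the list alone, adjusted p = 0.00015, adjusted p = 0.46 with an estimated correlation). The mitochondrial share of counts was 6.87% ± 0.84 in KO, 5.89% ± 0.63 in CE and 5.52% ± 0.08 in PTC lines and 5.17% ± 0.07 in wild type. The cardiac list had 0 of 11 that rose and 3 that fell (0 and 5 adjusted over the list alone), and its test and median (−0.46) were below 0 but its mean above (0.36). The amnion-like list had 0 of 16 that rose and 5 that fell (2 and 7 adjusted over the list alone), and its test was below 0 but its median (0.68) and mean (0.32) above. These 2 tests gave adjusted p = 0.014 and 0.037, and adjusted p = 0.42 and 0.49 with an estimated correlation.

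The ISL1 counts depended on the fit and on single libraries. DESeq2 called 1831 genes, the covariate fit 1801 and a fit without the 4 libraries highest in the syncytiotrophoblast list 3600, the last 2 chosen after the data were seen. Without CE replicate 1 the cardiac and amnion-like calls ended (adjusted p = 0.06 and 0.13), and the amnion-like one also without KO replicate 1 or 3 or PTC replicate 2 (adjusted p = 0.085, 0.11 and 0.11). The count of 635 was 373 and 349 without PTC replicates 1 and 3, and 212, 222 and 180 without wild-type replicates 1, 2 and 3.

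**Figure D5:**
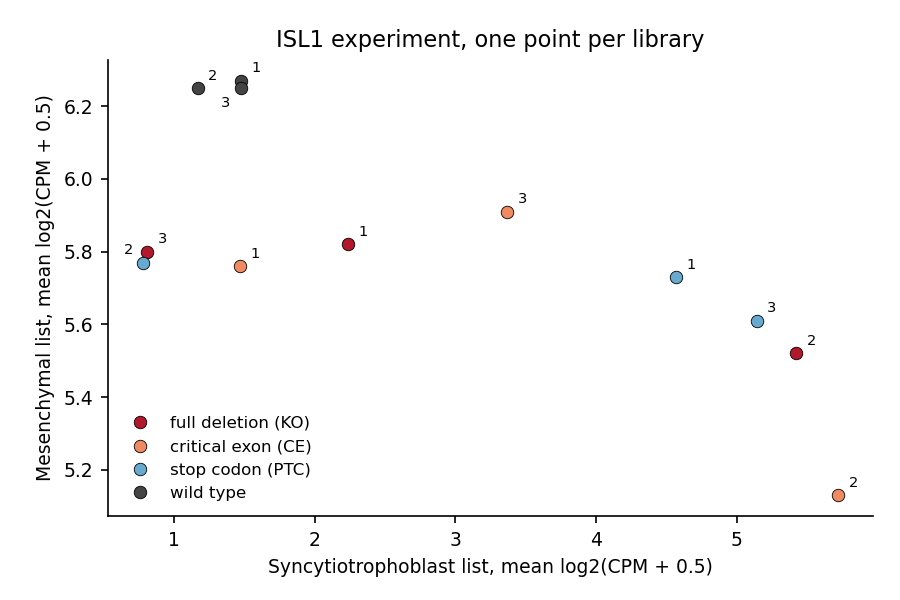
Mean log2(CPM + 0.5) of the mesenchymal list (y axis) against that of the syncytiotrophoblast list (x axis) in the 12 libraries of the ISL1 experiment, coloured by group and numbered by replicate. The 4 lines with the most syncytiotrophoblast transcripts have the fewest mesenchymal ones.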

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

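The splits of the wild types by oxygen and of the ISL1 lines against wild type were set after the calls of these comparisons were known.

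Results stand here because the same contrast gave different effects in 2 groups of samples, by a test of the difference itself. The effect of losing EPAS1 differed between 3% and 20% oxygen for 931 genes, and 1 of the 100 splits of the libraries, the real one, gave as many while the highest other gave 0. The other splits mix wild type with EPAS1 lines, so they test any difference between these lines. They cannot exclude chance for the difference between oxygen levels alone. The 10 genes with the smallest p had higher values at 3% relative to 20% oxygen, as log2 differences of 2.05 for VSIR, an immune checkpoint gene, 1.45 for RXYLT1, a glycosyltransferase gene, 2.69 for SERPINB7, 2.54 for SERPINB2, 2.02 for TMPRSS2, 1.61 for MTSS1, 1.89 for KYNU, 1.33 for VAV3, 2.06 for MISP3 and 1.27 for MEGF9. List medians of this difference were 0.84 for syncytiotrophoblast hormones and fusion, −0.64 for the amnion-like list, 0.48 for lipid handling, 0.65 for endoderm and 0.90 for the integrated stress response. With an estimated correlation none of these 5 lists passed (adjusted p = 0.48, 0.83, 0.61, 0.61 and 0.83). The amnion-like call (adjusted p = 0.042) also ended without KO replicate 1 or 3, CE replicate 1 or wild-type replicate 1 or 2 at 3% oxygen (adjusted p = 0.051, 0.051, 0.15, 0.094 and 0.23). At 20% oxygen it ended without KO replicate 1 or 2, CE replicate 2, PTC replicate 1 or 2 or wild-type replicate 1 or 3 (adjusted p = 0.059, 0.063, 0.092, 0.057, 0.054, 0.074 and 0.2). No technical explanation was tested for this difference, and day or incubator remains confounded with oxygen level.

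The effect of losing GCM1 differed from that of losing PPARG for 7966 genes, against 121 in the highest of the other splits, and 1 of 100 splits gave as many. The other splits mix GCM1 with PPARG lines, which raises the spread within groups and lowers their counts. They therefore cannot exclude chance for the difference in effect itself. Log2 differences were 4.56 for TRHDE-AS1, 3.80 for PWWP3B, −4.09 for GPR78, 3.17 for GAREM1, −3.04 for PTPRE, −3.94 for IQGAP2, −4.70 for CKMT1A, −3.02 for RELT, 2.87 for THSD7A and −3.52 for IL36RN. List medians were −1.76 for syncytiotrophoblast hormones and fusion, 0.66 for the cytotrophoblast list, −0.91 for mesenchymal, 0.86 for hypoxia, 0.87 for lipid handling, 0.36 for epithelial junctions, −1.33 for cardiac, −2.57 for endothelial and 0.75 for histones. With an estimated correlation the syncytiotrophoblast, cytotrophoblast, mesenchymal, hypoxia, junction and histone lists did not pass (adjusted p = 0.15, 0.15, 0.15, 0.44, 0.44 and 0.4), and the other 3 did. The hypoxia and mesenchymal lists were lower in the GCM1 than in the PPARG wild type (medians −0.67 and −0.53), and the hypoxia list did not pass for loss of GCM1 (adjusted p = 0.79), so the wild types' own difference enters these 2 values. The syncytiotrophoblast and cytotrophoblast lists were also called between these wild types, so that difference enters their values too. Both calls ended without GCM1 wild-type replicate 2 (camera adjusted p = 0.19 and 0.068). TRHDE-AS1 is antisense to TRHDE, so its reads may belong to that gene, which fell by 4.88 on the log2 scale with loss of PPARG; no test separated them, and with estimated counts the whole difference covered 6889 genes.

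The other comparisons were tested against other splits in the same way. The real split alone was as large, 1 of 100, for loss of GRHL1 (9789 genes, highest other 7067), POU2F3 (3957, 1615) and EPAS1 at 3% oxygen (6346, 5075). The same held for GCM1 (10476, 4326), PPARG (8606, 5459), oxygen in the EPAS1 lines (9875, 6681) and the EPAS1 strategies at 20% oxygen (8, 0). For these, the EPAS1 strategies aside, chance can be excluded at a share of 0.05, which was not corrected over the 21 comparisons. The 8 genes of those strategies are EPAS1 itself and 7 genes downstream within 300 kb. Chance is therefore not excluded for a difference away from that edit. The share was 2 of 100 for FOSB (1148, 1288), EPAS1 at 20% oxygen (91, 2397) and the FOSB strategies (26, 194). It was 4 of 100 for ISL1 (635, 11099). In each of these another split called more genes, so chance is not excluded at such uncorrected shares. The POU2F3 and GCM1 strategies also had 4 of 100 (2, highest other 2 for each). There 1 of the 2 genes is the targeted gene, so chance is not excluded either. The splits of EPAS1 at 20% oxygen, of the FOSB strategies and of ISL1 that called several times the real count point to a structure of the samples beyond their groups. Chance cannot be excluded for the strategies of GRHL1 (7, highest other 1658, 8 of 100), EPAS1 at 3% oxygen (9, 6980, 13 of 100) and PPARG (1, 885, 23 of 100), where such splits point to a structure of the samples as well. For the ISL1 strategies the real count was 0, so each of the 100 splits is as large and chance was not tested, while the highest other, 9092, points to such a structure too. For oxygen in wild type (9132, highest other 0) and the pair of wild types (611, highest other 0) the 10 splits are too few for a share under 0.05, with 1 as large in each.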

How the results depend on the processing

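The block for the EPAS1 effect by oxygen, and for ISL1 the covariate and the fit without 4 libraries, were chosen after the data were seen.

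Of the counts of called genes for loss of GRHL1, POU2F3, PPARG and GCM1, for oxygen, for EPAS1 at 3% oxygen, for GCM1 against PPARG and for the EPAS1 strategies at 20% oxygen, every one stayed within 1.5 times under DESeq2, its size factors, no filter, estimated counts and the 12 libraries alone where these were run. Scaling moved the median of all genes by less than 0.1 in each. Counts that moved further were as follows, and the cause was not tested. With DESeq2 they were 171 (GRHL1 strategies), 5 (POU2F3 strategies), 176 (FOSB strategies), 282 (EPAS1 at 20% oxygen), 32 (EPAS1 strategies at 3%), 1485 (EPAS1 by oxygen), 4 (GCM1 strategies), 113 (PPARG strategies), 990 (wild type against wild type), 1831 (ISL1) and 2 (ISL1 strategies). Without the filter they were 608 (EPAS1 by oxygen) and 4 (PPARG strategies), and with estimated counts 4 (GRHL1 strategies) and 79 (FOSB strategies). With the 12 libraries alone they were 745 (FOSB), 191 (EPAS1 at 20%) and 2 (PPARG strategies). ISL1 gave 1801 and 3600 with the covariate and without the 4 libraries, and its strategies 3 and 134.

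With the lines of the other 2 genes plus wild type as control FOSB had 6436 genes; that control has both more libraries and other genotypes, and the cause was not tested. This control reversed lists for POU2F3, syncytiotrophoblast (adjusted p = 0.53) and mesenchymal (1.3e-10), and for FOSB, amnion-like (0.97), hypoxia (0.0027), integrated stress response (0.031) and histones (0.00026). It reversed CDH2 for GRHL1 (−0.22) and, for POU2F3, KDR (−0.75), DCLK1 (0.21), COL3A1 (−0.70) and CDH11 (−0.33), and DCLK1 for FOSB (0.51). In TPM, PPARG in CE lines was at 97.3% of wild type.

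The replicate block gave 9674 genes for oxygen in wild type, 10342 in the mutants, 1182 for EPAS1 by oxygen and 736 for the wild types, all within 1.5 times. It ended 1 list call, that of pluripotency for oxygen in wild type (camera adjusted p = 0.052).

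Leaving out 1 library in turn gave, as lowest and highest counts, 8160 and 10413 for GRHL1, 490 (without wild-type replicate 3) and 4770 for POU2F3, 208 (wild-type replicate 1) and 1781 (PTC replicate 2) for FOSB, 7 (wild-type replicate 1) and 225 (KO replicate 1) for EPAS1 at 20% oxygen, 3771 (wild-type replicate 2) and 8868 for EPAS1 at 3%, 7089 and 8633 for oxygen in wild type, 9098 and 10761 in the mutants, 266 (wild-type replicate 2 at 3%) and 2292 (CE replicate 1 at 3%) for EPAS1 by oxygen, 8630 and 10899 for GCM1, 6336 and 8791 for PPARG, 6659 and 8371 for GCM1 against PPARG, 151 (GCM1 wild-type replicate 3) and 1772 (GCM1 wild-type replicate 1) for the wild types and 180 (wild-type replicate 3) and 949 for ISL1. For the strategies they were 4 and 3383 for GRHL1, 2 and 2 for POU2F3, 8 and 43 for FOSB, 8 and 14 for EPAS1 at 20%, 8 and 3949 at 3%, 2 and 3 for GCM1, 1 and 467 for PPARG and 0 and 0 for ISL1 in edgeR; the other libraries that moved a count by more than 1.5 times stand in the report. Of the calls of genes printed here, which leave out several that ended, and of lists, 19 of 158 and 33 of 122 ended in some such fit, and none changed sign.

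DESeq2's size factors kept all 122 list calls, and estimated counts 114. At the depth of these libraries a 1.5-fold change was recovered for 68% of simulated genes for GRHL1 but 12% for ISL1, so small changes in the ISL1 lines were often below detection.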

Other observations

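The tests of genes downstream of EPAS1, of a mislabelled library and of a share of cells among the ISL1 lines, and of the level of the shared wild types were chosen only after the result was seen.

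Loss of GRHL1 went with higher levels of several genes shared with the amnion, another early extraembryonic epithelium. GABRP, a GABA receptor gene, rose from 110 ± 24 to 337 ± 41.7 CPM (1.62 ± 0.19, adjusted p = 6.2e-07). VTCN1, an immune checkpoint gene, rose from 54.9 ± 11.2 to 124 ± 7.61 CPM (1.17 ± 0.12, adjusted p = 1e-08), while ANXA1, a gene of inflammation control, fell (−0.94 ± 0.14, adjusted p = 6.2e-06). Of 17 genes in the list 10 rose and 3 fell, also when adjusted over the list alone (median 0.64, adjusted p = 0.014, adjusted p = 0.29 with an estimated correlation). The list mean on the log2 scale was 5.24 to 5.61 in the GRHL1 lines and 4.64 to 4.86 in the shared wild type. In the PPARG wild type it was 5.46 to 5.64, so unedited cultures of that experiment reached the range of the GRHL1 lines. The GCM1 wild type, at 4.83 to 5.16, lay below that range.

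Loss of PPARG lowered genes of the extravillous trophoblast, the lineage that invades the uterus. HLA-G, its antigen-presenting gene, fell from 115 ± 5.17 to 31.6 ± 6.5 CPM (−1.86 ± 0.13, adjusted p = 2.9e-10). SERPINE1, a protease inhibitor gene, fell from 937 ± 90.9 to 147 ± 27.9 CPM (−2.68 ± 0.13, adjusted p = 8.2e-13). Of 18 genes 1 rose and 11 fell, also when adjusted over the list alone (median −0.75, adjusted p = 0.0002, adjusted p = 0.26 with an estimated correlation). The list mean on the log2 scale was 4.17 to 4.56 in the PPARG lines and 4.89 to 4.92 in their wild type. It was 4.26 to 4.78 in the GCM1 wild type, so unedited cultures of that experiment reached the range of the PPARG lines. The hypoxia response was lower too, with 1 of 34 genes that rose and 22 that fell (1 and 23 adjusted over the list alone, median −0.63, adjusted p = 9.1e-06, adjusted p = 0.41 with an estimated correlation). In it ANGPTL4, a lipase inhibitor gene, fell from 21.3 ± 2.2 to 4.83 ± 1.16 CPM (−2.16 ± 0.24, adjusted p = 6.1e-07). The mean of the hypoxia list was 4.97 to 5.39 in the PPARG lines and 5.66 to 5.69 in their wild type. In the GCM1 wild type it was 4.86 to 5.42, so the PPARG lines lay within the range of those unedited cultures.

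Loss of GCM1 lowered cardiac and second heart field genes, of which 0 of 12 rose and 8 fell, also when adjusted over the list alone (median −0.94, adjusted p = 0.019, adjusted p = 0.095 with an estimated correlation). TBX20, a heart muscle factor gene, fell from 32 ± 5.1 to 12.1 ± 3.37 CPM (−1.43 ± 0.19, adjusted p = 3.1e-06).

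Genes downstream of EPAS1 were counted higher in the KO lines than in the CE and PTC lines. An effect of losing EPAS1 itself is argued against by RHOQ, whose log2 ratio of CE and PTC lines to wild type was −0.14 ± 0.34 (SE) in the transcript estimates. Extra copies of the region would raise its genes alike, but the log2 ratio of KO to the other strategies was 5.06 ± 0.58 higher for LINC02583, which lies nearer to the edit and had 15 reads in the 12 libraries of those strategies, than for RHOQ. For the genes on the opposite strand (LINC01820, ATP6V1E2, RHOQ-AS1 and PIGF) the log2 ratio was 2.60 ± 0.27 in gene counts and −0.53 ± 0.12 in the transcript estimates, so reads from the strand of EPAS1 may have been counted for them. For RHOQ, higher in both (1.78 ± 0.23 and 2.22 ± 0.25), transcription running on past the deletion and a stronger promoter of its own remain open.

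Among the 9 ISL1-edited lines, syncytiotrophoblast transcripts varied from line to line. Their share, as a percent of the level in primitive syncytium wild types other than those at 3% oxygen over 25 genes, was 1.29, 57.7 and −0.299 in the KO lines, 0.00678, 82.4 and 7.0 in the CE lines and 28.1, −0.306 and 46.8 in the PTC lines, and CGA, the abundant hormone chain, reached 10000 CPM. A library of a primitive syncytium culture under an ISL1 label is argued against, since the lowest mesenchymal list mean of these lines was 5.13 on the log2 scale, and the primitive syncytium wild types ran from 2.69 to 3.70 and those at 3% oxygen to 4.36. RNA mixed in from primitive syncytium cultures cannot be told apart from a change within the cultures: the cytotrophoblast share divided by the syncytiotrophoblast share had a median of 0.57, below the bound of 0.67 set against mixing, but its range over 5 lines, 0.52 to 0.81, crosses that bound. The mesenchymal level fell as the share rose (Pearson r = −0.98, exact permutation p = 0.00021, adjusted 0.00041; Spearman rho = −0.88, exact permutation p = 0.0031, adjusted 0.0031; 2 relations; r = −0.91 without the 2 lines farthest from the median share), as a share of syncytiotrophoblast-like cells beside mesenchymal cells may give; loss of ISL1 as its origin was not tested.

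Mesenchymal genes were higher in the FOSB-edited lines than in the shared wild type. Chance values of the 3 shared wild-type libraries cannot be told apart from it by the covariance of fold changes between the 3 genes, at least 0.132 against 0.0581 in the highest simulation, since deviating wild types would raise that covariance too. A share of extraembryonic mesoderm-like cells would bring each mesenchymal gene in at 1 share of its level there, but the share ran from 0.394% for POSTN and 0.997% for the abundant COL1A1 to 27.2% for COL3A1, and its upper quartile was 4.27 times the lower. The reference was the wild type of the ISL1 experiment, from another culture scheme and library series. A share of mesodermal cells with another profile was therefore not tested and remains open. A low mesenchymal level of the shared wild types may contribute: 4 of the 9 FOSB-edited lines lay within the range of the other primitive syncytium wild types when those at 3% oxygen are left out (2.91 to 3.70) and 8 when they are included (up to 4.36), the shared ones lay at 2.69 to 3.03 and the FOSB lines at 3.36 to 4.48, so this cannot be told apart from an effect of FOSB, with library series confounded.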
